A study of Mus musculus with 18 samples.

How the data were processed

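The series holds 18 mRNA-seq libraries of mouse bone-marrow-derived macrophages after LPS, with 3 libraries for each of 2 genotype labels (WT and KO of Mkrn2) in each of 3 RNA sources (total, polysome and monosome RNA). Per the labels, polysome profiling separated the fractions and libraries were made with a SMARTer kit; strandedness is not stated, nor whether the replicates were separate cultures or animals. The authors deposited 1 table of 34745 genes with raw counts per gene for each library and, beside them, FPKM values. The processing notes name fastp 0.23.2, HISAT2 2.0.4 and StringTie 1.3.0 without saying what each did, and give no genome build. The deposited FPKM were checked to be the counts divided by a fixed gene length and the column total: the implied length differed by at most 0.071% between libraries over 9554 genes with a mean of at least 50 counts. FPKM were not used in any test. Gene positions in the table were compared with the GENCODE mouse annotation of the GRCm38 build: 34344 genes were found by identifier and 27776 of them (80.9%) had the same chromosome, start and end, and positions printed here are those of the table.

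Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the 6 groups (12782 genes), scaled by TMM, and fitted with 1 mean per group over all 18 libraries, followed by the quasi-likelihood F test (two-sided, prior degrees of freedom 3.41). P values were adjusted by Benjamini-Hochberg over the tested genes of a comparison, with a threshold of 0.05. Errors of log2 differences are standard errors of the fit, and CPM are TMM-scaled counts. Confidence intervals are at 95%. Library totals were 9190034 to 16711558 counts; TMM factors were 0.605 to 0.664 in monosome libraries and 1.24 to 1.30 in the others. Intervals of ratios of counts are exact Poisson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

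Before the data were examined, 6 comparisons were fixed: KO against WT in each of total, polysome and monosome RNA, the difference of the polysome-to-total and of the polysome-to-monosome ratio between genotypes, and polysome against monosome RNA in WT. So were 24 gene lists, 11 lists of cell type markers, the alternatives below and the rule for naming genes. A comparison of polysome with total RNA in WT was added after the counts were seen. The rule names Mkrn2, Il6 and Mkrn1, with other genes that are not reported here; up to 10 genes of the largest change each way among those past the threshold, at or above the median level and with no overlap between libraries (for ratios, with a sign kept when any library is left out); where fewer than 5 pass, the 5 of smallest p each way; and up to 4 members of each list of smallest p. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with at least 5 tested members (3 for markers), and again with the correlation estimated for each list. Of the marker lists, 6 had enough tested members.

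Alternatives were RLE size factors, no scaling beyond library size, no filter, a filter at a mean of 5 CPM, only the libraries of the groups compared, the replicate number as a block, voom with quality weights, DESeq2 1.42.0, an estimated inter-gene correlation for the lists, leaving out each library in turn, and a robust prior added after the counts were seen. Another pseudocount, meant for a case with normalised values alone, was not tried, since counts were available. The test was tried on simulated data with 200 planted changes per comparison: of genes changed 2-fold it called 82.1% in total RNA, 76.1% in polysome RNA, 88.1% in monosome RNA, 34.3% for the polysome-to-total ratio, 43.3% for the polysome-to-monosome ratio and 79.1% for polysome against monosome RNA in WT; of genes changed 1.5-fold it called 26.9%, 23.9%, 13.4%, 5.97%, 8.96% and 20.9%, with 3 to 10 false calls. The simulated counts had the spread of the trend with level, no spread particular to a gene, and a mean common to the 6 groups before the changes. Changes were planted in genes with a mean of at least 50 counts. The rates may therefore be too favourable for the real counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.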

Results

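Messenger RNA was sequenced from mouse macrophages that had been grown out of bone marrow with 20 ng/ml of M-CSF for 6 days and then exposed to 100 ng/ml of lipopolysaccharide (LPS) for 8 h. The RNA came from whole cells (total RNA), from the polysome fraction and from the monosome fraction. Polysomes are mRNAs loaded with several ribosomes, and monosomes are mRNAs on lone ribosomes. The fractions may hold other RNA too. Mitochondrially encoded genes took 3.39% to 4.91% of the counts in the monosome libraries and 1.47% to 2.19% in the others. Cells were wild type (WT) or labelled as knockouts (KO) of Mkrn2, the gene of an RNA-binding E3 ubiquitin ligase. Each genotype and fraction had 3 libraries, 18 in all. A library held 11402715 to 16711558 counts for total RNA, 13006294 to 15759370 for polysome RNA and 9190034 to 12606314 for monosome RNA. The first principal component, with 57.5% of the variance, separated the monosome libraries from the rest. Fth1, the ferritin heavy chain, took 15.2% to 18.5% of the counts in the monosome libraries and 1.78% to 3.29% in the others.

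Mkrn2 RNA remained at 0.772 to 0.901 of its WT level in the 3 fractions of the libraries labelled KO, and Il6, which encodes the cytokine IL-6, lay higher in their polysome RNA. Mkrn2 (ENSMUSG00000000439, chromosome 6, 115601902 to 115622624) stood at 64.3 ± 3.98 CPM (scaled counts; mean ± SD, n = 3) in WT and 57.1 ± 3.45 in KO-labelled total RNA. In polysome RNA it stood at 95.1 ± 5.4 and 85.6 ± 5.22, and in monosome RNA at 89.2 ± 3.36 and 68.8 ± 5.85. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) stood at 65.3 ± 1.54 CPM in the WT polysome libraries and 122 ± 32.3 in those labelled KO. The difference was 1.87-fold, with a 95% interval of 1.49 to 2.34. That interval takes its spread from all 18 libraries and may be too narrow, given the wide spread of the KO-labelled polysome libraries. All 3 KO-labelled polysome libraries, with 1676, 2081 and 3005 counts of Il6, lay above the 3 WT libraries, which had 1181, 1291 and 1161. In total RNA Il6 stood at 97 ± 10.7 CPM in WT and 107 ± 13.2 in KO-labelled libraries, and in monosome RNA at 368 ± 35.6 and 310 ± 12.4.

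By edgeR's quasi-likelihood test over 12782 genes, the log2 difference of Mkrn2 was -0.17 ± 0.08 (SE) in total RNA, -0.15 ± 0.08 in polysome RNA and -0.37 ± 0.08 in monosome RNA, with Benjamini-Hochberg adjusted p of 0.855, 0.79 and 0.086. The intervals of the fold were 0.788 to 1, 0.8 to 1.01 and 0.684 to 0.871. Mkrn2 passed the threshold of 0.05 in monosome RNA with DESeq2 (-0.37, adjusted p = 0.00945) and without scaling beyond library size (-0.41, adjusted p = 0.0382), and its adjusted p over all settings tried ran from 0.00945 to 0.662. The paralog Mkrn1 differed by -0.07 ± 0.06, -0.06 ± 0.06 and 0.05 ± 0.06 in the 3 fractions, none past the threshold. Il6 did not pass the threshold in polysome RNA (log2 difference 0.90 ± 0.15, adjusted p = 0.0551), total RNA (0.15 ± 0.15, adjusted p = 1) or monosome RNA (-0.25 ± 0.15, adjusted p = 0.57). In polysome RNA the Il6 difference passed with no filter on low counts, a stricter filter, a robust prior, voom with quality weights and DESeq2, and its adjusted p over the settings ran from 0.000102 to 0.403. Without KO polysome replicate 1 it was 1.10 (adjusted p = 0.000778), and without KO polysome replicate 3 it was 0.72 (adjusted p = 0.111).

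**Figure D1:**
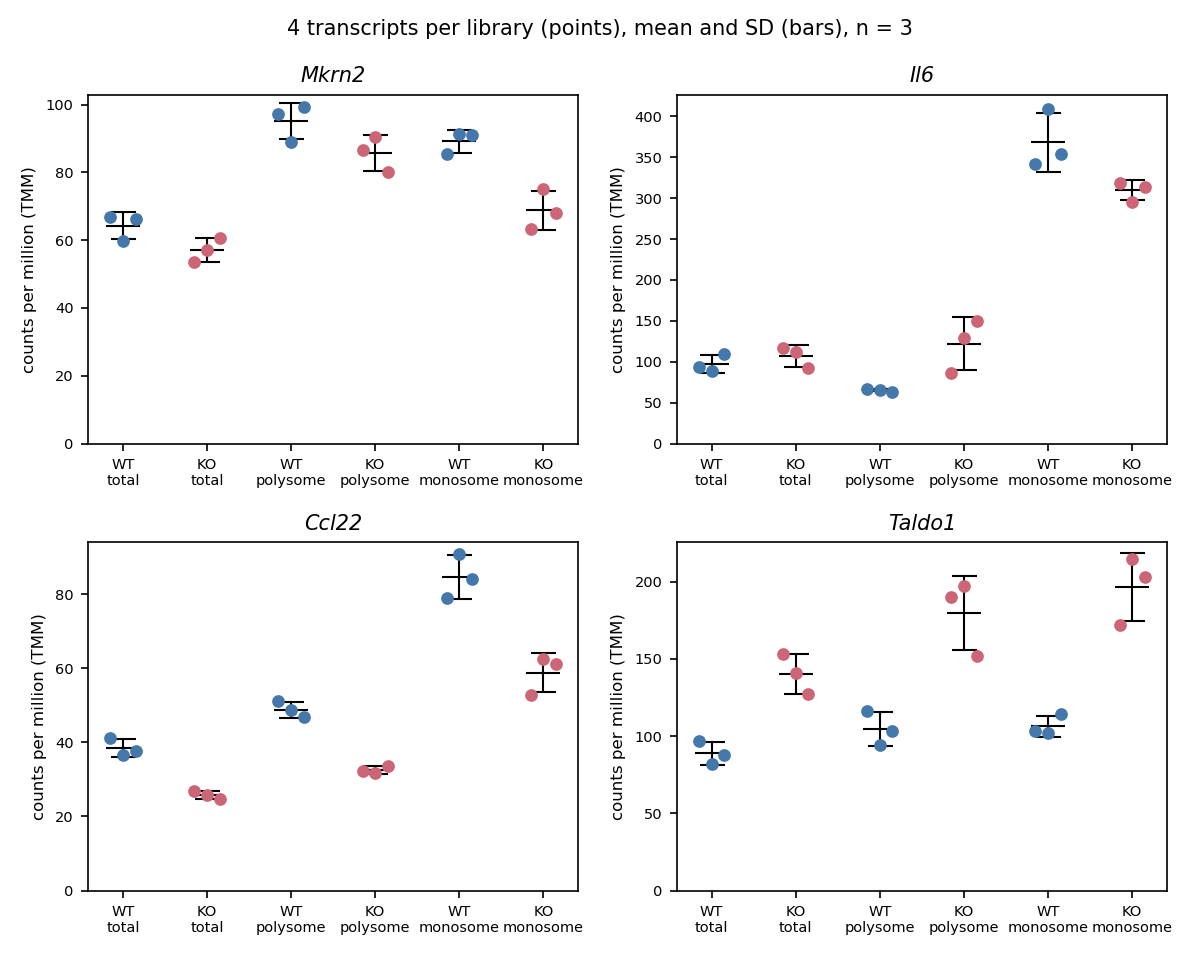
CPM after TMM scaling (y axis) of Mkrn2, Il6, Ccl22 and Taldo1 in the 6 groups of libraries (x axis; WT blue, KO-labelled red). Points are libraries, and bars give the mean and SD of 3. Mkrn2 keeps group means of 57.1 to 85.6 CPM in the libraries labelled KO, and all 3 KO-labelled polysome libraries lie above the WT ones for Il6.

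The comparison of total RNA asks which transcripts differ in amount between the genotype labels after 8 h of LPS. Rsu1, which encodes a Ras suppressor protein of cell adhesions, and Ccl22, a chemokine that attracts regulatory T cells, were lower in the KO-labelled libraries. Rsu1 (ENSMUSG00000026727, chromosome 2, 13076821 to 13271415) fell from 46.5 ± 2.43 to 25 ± 1.95 CPM (n = 3 each), and Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) from 38.5 ± 2.48 to 25.8 ± 1.19. For both genes all 3 KO-labelled libraries lay below all 3 WT libraries, which the naming rule requires. Of 9788 genes with a mean of at least 50 counts in total RNA, 1365 (13.9%) lacked overlap between the labels. Genes of the integrated stress response and of the NRF2 antioxidant response were higher as groups, and the mRNAs encoded in mitochondrial DNA were lower, each by a small amount. With an estimated correlation none of these 3 lists passed (adjusted p = 0.285, 0.754 and 0.754).

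In that test 2 genes passed, 0 higher and 2 lower: Rsu1 with a log2 difference of -0.90 ± 0.10 (adjusted p = 0.00228) and Ccl22 with -0.58 ± 0.08 (adjusted p = 0.0234). The count at an unadjusted p under 0.05 was 747, and voom with quality weights called 67 genes (37 higher and 30 lower) and DESeq2 32 (19 higher and 13 lower). Next in rank, and not past the threshold, came Il17ra, a receptor of IL-17 (0.50 ± 0.09), Taldo1, the transaldolase of the pentose phosphate pathway (0.66 ± 0.12), Etf1, the translation release factor (0.32 ± 0.06), Tlk2 (0.42 ± 0.08), the transcription factor Klf4 (-0.54 ± 0.09) and Tmem243 (-0.50 ± 0.10). Of the integrated stress response list, 23 of 25 tested members had a positive difference, with a median of 0.14. That list passed camera with adjusted p = 0.000313, but had adjusted p = 0.285 with an estimated correlation. It had 0 members past the threshold over all genes and 1 adjusted over the list alone, and examples are the cystine transporter Slc7a11 (0.58 ± 0.12), the glycyl-tRNA synthetase Gars (0.24 ± 0.08) and Chac1 (0.43 ± 0.16). In the NRF2 list 17 of 20 members were positive, with a median of 0.13 and 3 higher adjusted over the list alone, among them Taldo1, Slc7a11 and the thioredoxin reductase Txnrd1 (0.30 ± 0.08). Its adjusted p was 0.00203, and 0.754 with an estimated correlation. In the list of mitochondrially encoded mRNAs 12 of 13 were negative with a median of -0.18, among them mt-Nd3 (-0.31 ± 0.18), with adjusted p = 0.0183, and 0.754 with an estimated correlation. The LPS-induced cytokines did not pass as a list (16 of 24 positive, median 0.13, adjusted p = 0.192), with 3 higher and 1 lower adjusted over the list alone and values of 0.37 ± 0.08 for Tnfsf9, 0.49 ± 0.14 for Csf3 and -0.93 ± 0.21 for Ifnb1. Chemokines did not pass either (12 of 19 negative, median -0.06, adjusted p = 0.156), and Ccl6 (0.31 ± 0.09) differed in sign from Ccl22.

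Markers of stromal cells differed with the same labels: all 8 were higher in KO-labelled total RNA, with a median of 0.43 and adjusted p = 4.28e-09, and 0.0451 with an estimated correlation. Col1a2 stood at 84.3 ± 13.6 CPM in WT and 116 ± 5.95 in KO-labelled libraries, beside 3950 ± 332 and 4190 ± 18.7 for the macrophage gene Lyz2. The markers of macrophages (median -0.03), osteoclasts (0.00), B cells (0.18), dendritic cells (0.06) and megakaryocytes (0.52) did not pass, and the other 5 marker lists had too few tested members. With the replicate number as a block 0 genes passed (Rsu1 adjusted p = 0.0896, Ccl22 also 0.0896), and with the total RNA libraries alone 1 gene passed, with adjusted p of 0.0506 for Rsu1 and 0.175 for Ccl22. Without a filter 1 gene passed, and Ccl22 had adjusted p = 0.0914. The count was 1 without WT total replicate 2, 6 without KO total replicate 1, 1 without KO total replicate 2 and 5 without KO total replicate 3, and of the 6 refits without a library Ccl22 passed in 1, that without KO total replicate 1. Its adjusted p was 0.148, 0.0555 and 0.0786 without WT total replicates 1, 2 and 3, and 0.202 and 0.0721 without KO total replicates 2 and 3.

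The comparison of polysome RNA asks which transcripts differ between the labels in the polysome fraction. Taldo1 (ENSMUSG00000025503, chromosome 7, 141392199 to 141402968) was higher in the KO-labelled polysome libraries, at 180 ± 24.3 CPM against 105 ± 11 (n = 3 each), and Ccl22 was lower, at 32.5 ± 1.07 against 48.8 ± 2.16. Neither gene's libraries overlapped between the labels, which the naming rule requires. Of 9917 genes with a mean of at least 50 counts in polysome RNA, 1580 (15.9%) lacked such overlap. Antioxidant genes of NRF2, lysosomal genes and genes of the integrated stress response were higher as groups by small amounts, but with an estimated correlation none of the 3 lists passed (adjusted p = 0.275, 0.311 and 0.275).

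In polysome RNA 2 genes passed, 1 higher and 1 lower: Taldo1 with 0.78 ± 0.12 (adjusted p = 0.0414) and Ccl22 with -0.59 ± 0.08 (adjusted p = 0.0357). The count at an unadjusted p under 0.05 was 893, with 26 calls by voom with quality weights (18 higher and 8 lower) and 55 by DESeq2 (35 higher and 20 lower). Il17ra (0.54 ± 0.09, adjusted p = 0.0523), Pigs, an enzyme subunit of GPI anchor attachment (0.51 ± 0.09), the vesicle GTPase Arf1 (0.30 ± 0.05), Klf4 (-0.57 ± 0.09, adjusted p = 0.0535), Tmem243 (-0.55 ± 0.10) and the vesicle protein Vamp3 (-0.35 ± 0.07) were next in rank and did not pass. In the NRF2 list 16 of 20 members were positive (median 0.10), 1 passed over all genes and 3 adjusted over the list alone, with Taldo1, Slc7a11 (0.60 ± 0.12) and Txnrd1 (0.26 ± 0.08) of smallest p. Its adjusted p was 9.18e-05, and 0.275 with an estimated correlation. Among lysosomal genes 26 of 31 were positive (median 0.10), with 0 past the threshold over all genes and 5 adjusted over the list alone; the membrane protein Scarb2 had 0.29 ± 0.09 and Psap, the prosaposin, 0.26 ± 0.08. The lysosome list had adjusted p = 0.000357, and 0.311 with an estimated correlation. In the integrated stress response list 20 of 25 were positive (median 0.15), with Slc7a11 and the folate enzyme Mthfd2 (0.19 ± 0.07) of smallest p, and it had adjusted p = 0.000839, and 0.275 with an estimated correlation. The LPS-induced cytokines did not pass as a list (14 of 24 positive, median 0.03, adjusted p = 0.0787), with 0 members past the threshold over all genes and 4 higher adjusted over the list alone. Il6 led that list, followed by Tnfsf9 (0.31 ± 0.08), Il1a (0.31 ± 0.09) and Csf3 (0.46 ± 0.14).

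The stromal markers were again higher in the KO-labelled libraries (8 of 8, median 0.46, adjusted p = 2.49e-08, and 0.0619 with an estimated correlation), with Col1a2 at 38.4 ± 4.97 CPM in WT and 53.7 ± 5.72. With the polysome libraries alone 8 genes passed, but the adjusted p was 0.168 for Taldo1 and 0.0659 for Ccl22, and with the replicate number as a block 4 passed, with 0.0814 for Taldo1. The count was 1 without WT polysome replicate 1, 1 without WT polysome replicate 2, 6 without WT polysome replicate 3, 5 without KO polysome replicate 1 and 4 without KO polysome replicate 3, and Taldo1 passed without KO polysome replicate 3 alone. Its adjusted p was 0.0602, 0.115 and 0.0943 without WT polysome replicates 1, 2 and 3, and 0.1 and 0.144 without KO polysome replicates 1 and 2; that of Ccl22 was 0.07 and 0.0911 without WT polysome replicates 1 and 2, and 0.0586 and 0.105 without KO polysome replicates 1 and 2.

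The comparison of monosome RNA asks which transcripts differ between the labels in the monosome fraction, which may hold RNA other than mRNAs on lone ribosomes. Hk1, the hexokinase of the first step of glycolysis, fell 7.08-fold in the KO-labelled monosome libraries, from 84.9 ± 0.758 to 12 ± 1.14 CPM (n = 3 each). In total RNA it stood at 134 ± 6.54 and 115 ± 7.39, and in polysome RNA at 108 ± 0.991 and 91 ± 3.35. The chromatin protein Phf3 fell 4-fold, the transcriptional coactivator Trip4 4.13-fold and the nuclear import receptor Kpna6 2.05-fold. The splicing cofactor Srrm1 rose 4.89-fold, the solute carrier Slc35f6 4.07-fold and the amino acid transporter Slc7a7 2.19-fold. Ccl22 fell and Taldo1 rose in this fraction too, as did the release factor Etf1, the chemokine Ccl6, the kinase Sgk1 and Cltc, the clathrin heavy chain.

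In monosome RNA 32 genes passed, 16 higher and 16 lower, against 1495 at an unadjusted p under 0.05. The fit took the spread of a gene from all 18 libraries together. Between replicates, counts differed by a chi-square per degree of freedom of 15.9 to 40.1 in monosome RNA. It was 12.2 to 18.4 in total and 16 to 21.5 in polysome RNA, so the pooled spread may be too small here. With the monosome libraries grouped otherwise than by label, 5 to 23 genes passed. The 10 largest each way were taken among called genes at or above the median level and with no overlap between libraries, which leaves out some larger changes. Of these, the lower genes were Hk1 (ENSMUSG00000037012, chromosome 10, 62268855 to 62379908) with a log2 difference of -2.82 ± 0.08 (adjusted p = 4.67e-12), Phf3 with -2.0 ± 0.14, Trip4 with -2.05 ± 0.19, Kpna6 with -1.03 ± 0.12, the transcription factor Tcf4 with -1.70 ± 0.29, Vezt with -1.49 ± 0.28, the kinase Mark2 with -1.19 ± 0.23 and Glipr1 with -0.60 ± 0.10. Dgcr2, also lower, had 0, 0 and 15 counts in the KO-labelled and 88, 144 and 138 in the WT libraries, a ratio of 0.0364 with a counting interval of 0.0201 to 0.0608. The higher genes were Srrm1 with 2.29 ± 0.36, Slc35f6 with 2.03 ± 0.32, the histone methyltransferase Setdb1 with 1.40 ± 0.27, Slc7a7 with 1.13 ± 0.17, Ppp1r8 with 1.03 ± 0.13, Dopey1 with 0.81 ± 0.14, Sgk1 with 0.57 ± 0.07 and Cltc with 0.46 ± 0.08. Srrm1 stood at 83.9, 87.4 and 19.8 CPM in the KO-labelled libraries. Taldo1 had 0.89 ± 0.12 (adjusted p = 0.0022), Ccl22 -0.53 ± 0.08 (0.011), Klf4 -0.49 ± 0.10 (0.0477), Etf1 0.42 ± 0.06 (0.00697) and Ccl6 0.53 ± 0.09 (0.0203). Of the 33 genes called in at least 1 fraction, 18 had the same sign in all 3, and Ccl22 was the 1 gene called in all 3.

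The NRF2 list was higher in monosome RNA (17 of 20 positive, median 0.17, 1 member past the threshold over all genes and 3 adjusted over the list alone, adjusted p = 0.00127, and 0.845 with an estimated correlation), with Slc7a11 at 0.44 ± 0.12 and Nfe2l2, which encodes NRF2 itself, at 0.21 ± 0.07. The glycolysis and hypoxia list was lower by its test (adjusted p = 0.00248, and 0.845 with an estimated correlation), but 1 of its 24 members passed, which was Hk1, while the median was -0.04 and Bnip3, second in rank, had -0.40 ± 0.16. The integrated stress response did not pass in this fraction (13 of 25 positive, median 0.05, adjusted p = 0.445), nor did the LPS-induced cytokines (15 of 24 positive, median 0.09, adjusted p = 0.438). The stromal markers were higher (8 of 8, median 0.59, adjusted p = 2.53e-09, and 0.0432 with an estimated correlation), with Col1a2 at 53.9 ± 4.51 CPM in WT and 76 ± 6.78 in KO-labelled libraries.

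Hk1 and Phf3 passed under all settings, and the adjusted p of Hk1 was 0.000231 at most. All settings start from the same counts per gene, so they do not bear on how reads were assigned to genes. With the monosome libraries alone 10 genes passed, and Trip4 (adjusted p = 0.0707), Taldo1 (0.0707), Kpna6 (0.345), Slc7a7 (0.345), Dgcr2 (0.345), Ccl22 (0.487), Srrm1 (0.656) and Slc35f6 (0.662) did not. Nor did Sgk1 (0.233), Ppp1r8 (0.332), Etf1 (0.455), Ccl6 (0.49), Glipr1 (0.636), Mark2 (0.662), Klf4 (0.662), Dopey1 (0.662), Cltc (0.662) and Setdb1 (0.672). Without scaling beyond library size 10 genes passed as higher and 22 as lower (31.2% higher against 50%); DESeq2 called 118 genes (64 higher and 54 lower). Voom with quality weights called 15, without Ccl6 (adjusted p = 0.0544), Dgcr2 (0.0639), Mark2 (0.102), Klf4 (0.102), Tcf4 (0.11), Srrm1 (0.174), Setdb1 (0.174) and Vezt (0.247). The fit with a replicate block called 19, without Srrm1 (0.0504), Dopey1 (0.0573), Etf1 (0.0688), Vezt (0.114), Cltc (0.121) and Setdb1 (0.166). Without scaling Klf4, Setdb1 and Dopey1 (0.0579 each) and Cltc (0.0822) did not pass, without a filter Klf4 (0.0674) and Cltc (0.0644), and with a robust prior Vezt (0.0516) and Setdb1 (0.0529). Slc35f6 stood at 29.7, 10.5 and 7.44 CPM in the WT libraries, and its log2 difference was 2.83 without WT monosome replicate 1. The count was 71 without WT monosome replicate 1, 56 without WT monosome replicate 2 and 52 without KO monosome replicate 3. Without WT monosome replicate 1, Vezt (adjusted p = 0.0514) and Klf4 (0.0813) did not pass, and without replicate 2 Vezt (0.103), Mark2 (0.112), Klf4 (0.0922), Setdb1 (0.129) and Cltc (0.079) did not. Without WT monosome replicate 3 this held for Tcf4 (0.0517), Vezt (0.0577), Mark2 (0.11), Glipr1 (0.0616), Setdb1 (0.113), Dopey1 (0.0744) and Cltc (0.0782). Without KO monosome replicate 1 it held for Tcf4 (0.0671), Vezt (0.0993), Mark2 (0.0907), Glipr1 (0.0662) and Dopey1 (0.0671), and without KO monosome replicate 2 for those 5 (0.0646, 0.102, 0.113, 0.0621 and 0.0646), Klf4 (0.135), Setdb1 (0.12) and Cltc (0.0927). Without KO monosome replicate 3 it held for Vezt (0.0777), Klf4 (0.114), Setdb1 (0.105), Ccl6 (0.0552) and Cltc (0.0552), and Dgcr2, then with no KO-labelled count, had no finite ratio.

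**Figure D2:**
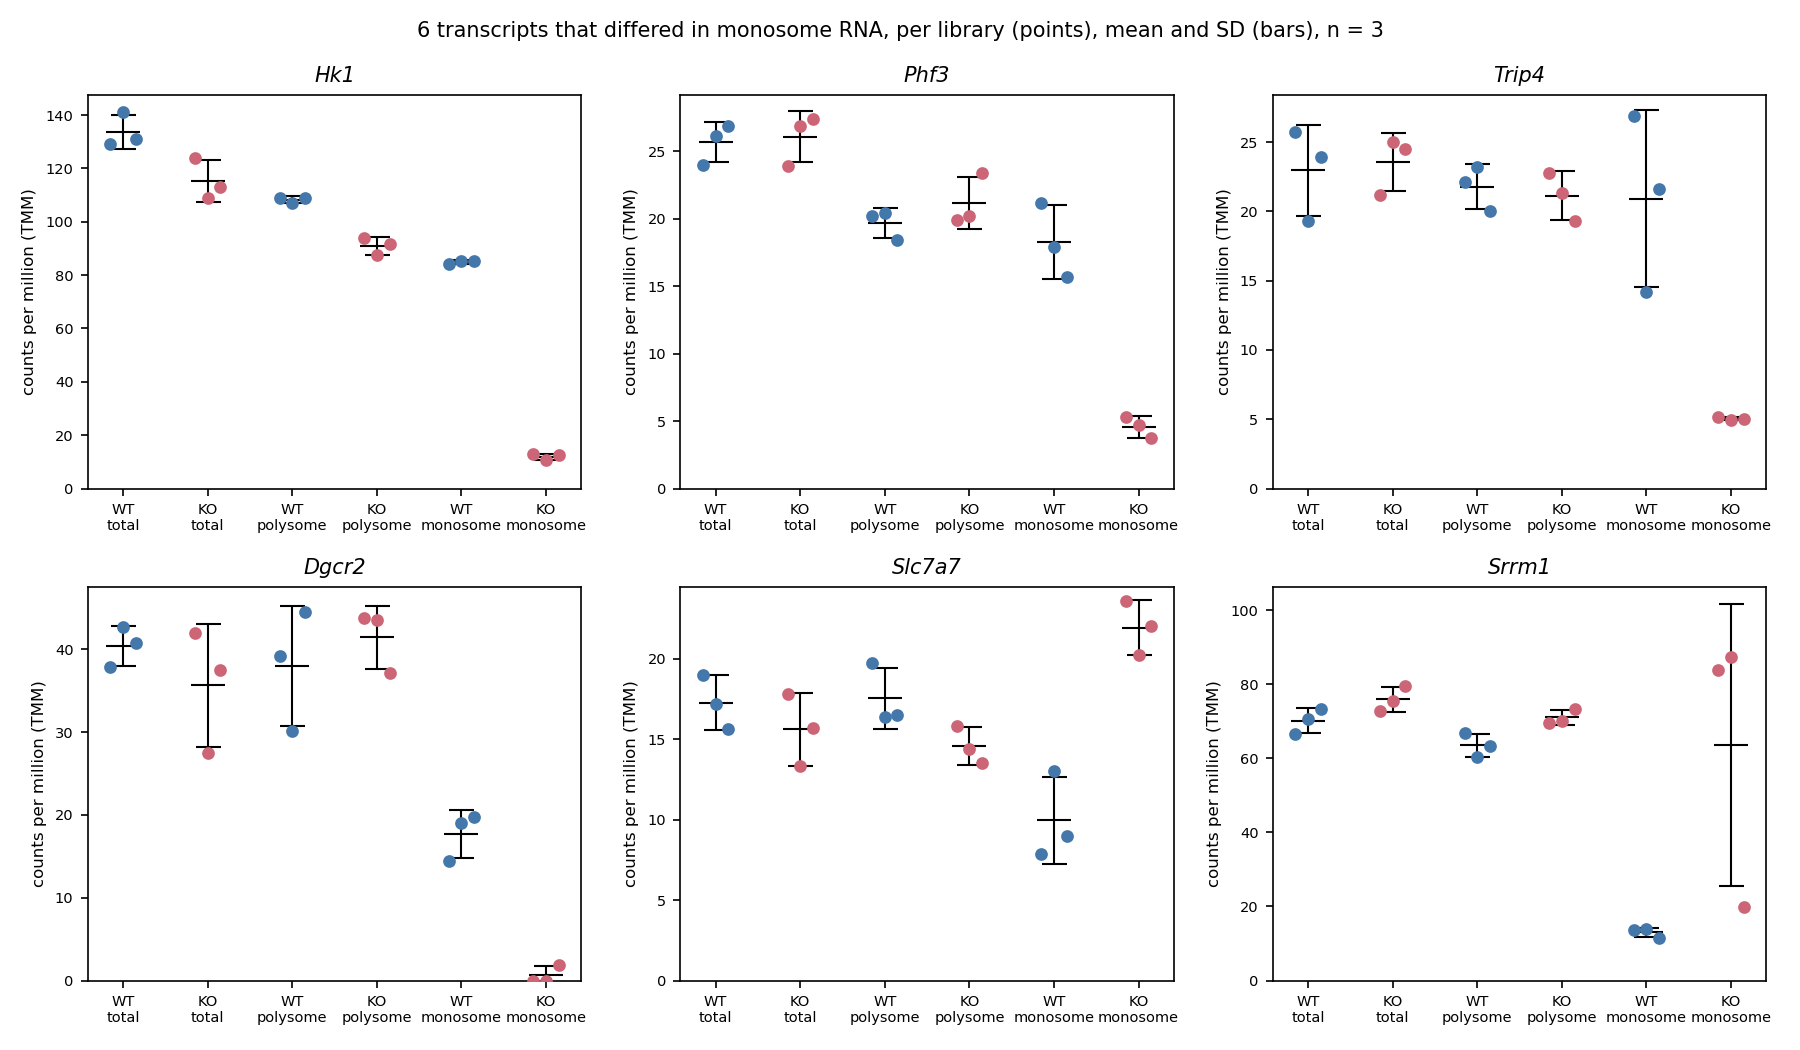
CPM after TMM scaling (y axis) of Hk1, Phf3, Trip4, Dgcr2, Slc7a7 and Srrm1 in the 6 groups of libraries (x axis; WT blue, KO-labelled red). Points are libraries, and bars give the mean and SD of 3, with lower bars ending at the axis. Hk1 stands at 12 CPM in the KO-labelled monosome group and between 84.9 and 134 CPM in the other groups, and Srrm1 has 1 of its 3 KO-labelled monosome libraries at 19.8 CPM.

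The polysome-to-total ratio asks whether ribosome loading, rather than the amount of a transcript, differs between the labels. No gene passed. Il6 had the ratio 1.69-fold higher with the KO label, with a 95% interval of 1.23 to 2.32. That interval uses the pooled spread and may be too narrow for Il6. The largest cytokine after Il6 was Ifnb1, the interferon beta gene, with a log2 difference of 0.70 ± 0.29. The lysosomal genes were higher as a group, with 24 of 31 positive and a median of 0.09, but had adjusted p = 0.929 with an estimated correlation.

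By edgeR's quasi-likelihood test 0 genes passed for this ratio, against 229 at an unadjusted p under 0.05. Voom with quality weights called 1 and DESeq2 3 (2 higher and 1 lower). Of 12782 tested genes, 229 are fewer than that cutoff gives when nothing differs, so the test may be too strict for this ratio. The 0 calls therefore do not show that loading is alike, and the cause was not tested. The Il6 difference was 0.75 ± 0.21 (unadjusted p = 0.00301, adjusted p = 1). Rsu1, lower in total RNA and at 25.2 ± 3.49 against 28.9 ± 1.98 CPM in polysome RNA, had 0.70 ± 0.14 and passed with DESeq2 (adjusted p = 0.035, against a range of 0.035 to 1 over all settings). Tm9sf1 had -0.79 ± 0.19. The lysosome list passed (adjusted p = 0.0145, and 0.929 with an estimated correlation), with 0 of its members past the threshold over all genes and 0 adjusted over the list alone; Hexa had 0.24 ± 0.11 and Scarb2 0.24 ± 0.12. The LPS-induced cytokines did not pass (13 of 24 positive, median 0.02, adjusted p = 0.846), and the stromal markers had a median of 0.06. Counts were 4 without KO total replicate 1, 3 without KO total replicate 3 and 1 without KO polysome replicate 1, 2 or 3. On simulated data with planted changes and no spread particular to a gene, 34.3% of genes changed 2-fold were called for this ratio. A change of that size can thus go undetected with 3 libraries a group.

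The polysome-to-monosome ratio asks the same of heavy against light ribosome loading. Hk1 had the ratio 5.95-fold higher with the KO label, Phf3 4.29-fold, Trip4 4.01-fold and Kpna6 2.15-fold, and Slc7a7 had it 2.63-fold lower. For each of these 5 genes the group means in polysome RNA differed by less than in monosome RNA. Il6 had the ratio 2.22-fold higher, with a 95% interval of 1.62 to 3.05 that also uses the pooled spread, and did not pass.

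Here 7 genes passed, 6 higher and 1 lower, against 678 at an unadjusted p under 0.05 and 27 by DESeq2 (16 higher and 11 lower). Of 100 splits of the libraries, the real one included, 50 gave at least 7 genes, so the adjusted p values may be too small. The log2 differences were 2.57 ± 0.11 for Hk1 (adjusted p = 1.29e-09), 2.10 ± 0.19 for Phf3 (3.29e-05), 2.0 ± 0.26 for Trip4 (0.00301), 1.11 ± 0.16 for Kpna6 (0.0118) and -1.39 ± 0.23 for Slc7a7 (0.0327). Dgcr2, with 0 counts in 2 of the KO-labelled monosome libraries, and Aarsd1, with 2, 1 and 1 counts there against 37, 40 and 40 in WT, were the other 2 called genes. Aarsd1 lies outside the rule for named genes and was added after its values were seen; its monosome ratio was 0.0307 with a counting interval of 0.00822 to 0.0806. Il6 had 1.15 ± 0.21 (adjusted p = 0.116, and 0.00124 to 0.444 over all settings), and it passed with DESeq2 (1.14) and without KO polysome replicate 1 (1.34, adjusted p = 0.00131). The glycolysis and hypoxia list was higher (16 of 24 positive, median 0.08, adjusted p = 0.000817, and 0.628 with an estimated correlation), with Hk1 its 1 called member. Slc7a7 did not pass with only the groups compared (adjusted p = 0.0785), with a replicate block (0.0821) or with voom (0.0631), and Dgcr2 did not under the same settings (0.0771, 0.0732 and 0.124). Slc7a7 had 0.118, 0.0578 and 0.0526 without WT polysome replicates 1, 2 and 3, 0.0973 and 0.129 without KO polysome replicates 2 and 3, 0.0837 without WT monosome replicate 3 and 0.071 without KO monosome replicate 1. Kpna6 had 0.102 with only the groups compared and 0.0505 without WT polysome replicate 2. The count was 19 without WT monosome replicate 1, 18 without WT monosome replicate 2, and 12, 16 and 19 without KO monosome replicates 1, 2 and 3.

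The last comparison asks how transcripts of WT macrophages divide between polysomes and monosomes after LPS. Relative to all genes, mRNAs of ribosomal proteins, chemokines, LPS-induced cytokines and ferritin were far more abundant in monosome RNA. Of 78 ribosomal protein genes, 73 were lower in polysome RNA and 0 higher, with a median log2 difference of -1.55, and Rplp0 stood at 6330 ± 704 CPM in monosome and 1110 ± 15.9 in polysome RNA (n = 3 each). Of 19 chemokines, 17 were lower and 0 higher (median -1.35), as for Cxcl10, a ligand of CXCR3, at 17900 ± 1660 and 3850 ± 244 CPM. Of 24 LPS-induced cytokines, 18 were lower and 3 higher (median -0.74, but 0.26 without scaling beyond library size, where the median of all genes moved to 1.01), and Il6 was 5.64-fold lower, Il1a 5.06-fold and Il1b 4.52-fold. The ferritin chains Fth1 and Ftl1 were 14.7-fold and 11.9-fold lower.

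In this comparison 7059 genes passed, 3347 higher and 3712 lower (47.4% higher), against 7641 at an unadjusted p under 0.05. Among the largest changes at or above the median level, Fth1 had -3.88 ± 0.16, Ftl1 -3.58 ± 0.43, the stress protein gene Nupr1 -3.56 ± 0.14 and mt-Atp6 -4.32 ± 0.59. The largest increases included Smg5, a factor of nonsense-mediated decay (4.33 ± 0.16), the deubiquitinase Bap1 (3.27 ± 0.50) and the lysosomal enzyme Idua (3.04 ± 0.54). Il6 had -2.50 ± 0.16 (adjusted p = 4.05e-09), Rplp1 -2.90 ± 0.11, Rpl12 -2.67 ± 0.10, Ccl6 -2.57 ± 0.10 and Ccl9 -2.24 ± 0.09. Camera called 13 of the 24 lists, all lower, and those of ribosomal proteins (adjusted p = 1.06e-41, and 0.0342 with an estimated correlation), chemokines (7.26e-18, and 0.0287) and LPS-induced cytokines (3.62e-05, and 0.0396) also held with an estimated correlation. All 13 mitochondrially encoded mRNAs were lower (median -2.31, adjusted p = 3.53e-11, and 0.126 with an estimated correlation), mt-Nd1 by -3.34 ± 0.16. The mitochondrial ribosomal proteins, with 27 of 36 lower and 2 higher (median -0.73), had adjusted p = 9.62e-07, and 0.317 with an estimated correlation, with Mrps15 at -2.22 ± 0.10. Of the interferon-stimulated genes 26 of 44 were lower and 6 higher (median -0.37, adjusted p = 2.63e-05, and 0.0628 with an estimated correlation), Ifi205 by -2.33 ± 0.08. The other 7 called lists were the respiratory chain (median -0.32), core histones (-1.09), NRF2 (-0.35), noncoding RNAs (-0.92), apoptosis and inflammasome (-0.20), ubiquitin and proteasome (-0.34) and arachidonate and nitric oxide (-0.20), with adjusted p with an estimated correlation from 0.126 to 0.53. Members of these with the smallest p were Ubb, a ubiquitin gene (-2.50 ± 0.10), and Casp1, the inflammasome protease (-1.50 ± 0.07). Adjusted over the list alone, 73 ribosomal protein genes, 18 chemokines and 18 cytokines were lower.

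The translation factors did not pass as a list and went both ways: Tpt1 had -2.79 ± 0.07, and the initiation factors Eif4h and Eif4b had 1.19 ± 0.07 and 1.15 ± 0.09. In the integrated stress response list, which did not pass (median 0.26, adjusted p = 0.439), 9 members rose and 5 fell, with Ppp1r15b, a regulator of the eIF2 phosphatase, at 1.26 ± 0.09 and Ddit3, the transcription factor CHOP, at -2.21 ± 0.10. Macrophage and osteoclast markers were lower in polysome RNA (9 of 11 tested genes, as the symbol Itgam stands for 2 genes, and 4 of 5, adjusted p = 0.0319 and 0.000628, and 0.0602 and 0.0412 with an estimated correlation). Without scaling beyond library size 9221 of 9950 calls (92.7%) were higher, and the list medians relative to that of all genes were -1.55 for ribosomal proteins, -1.36 for chemokines and -0.75 for cytokines. Before that shift was taken off, the medians of ribosomal proteins (-0.54), chemokines (-0.34), mitochondrially encoded mRNAs (-1.29) and core histones (-0.07) stayed negative, and those of the other 9 called lists were positive, such as the mitochondrial ribosomal proteins (0.28), noncoding RNAs (0.08) and interferon-stimulated genes (0.64).

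**Figure D3:**
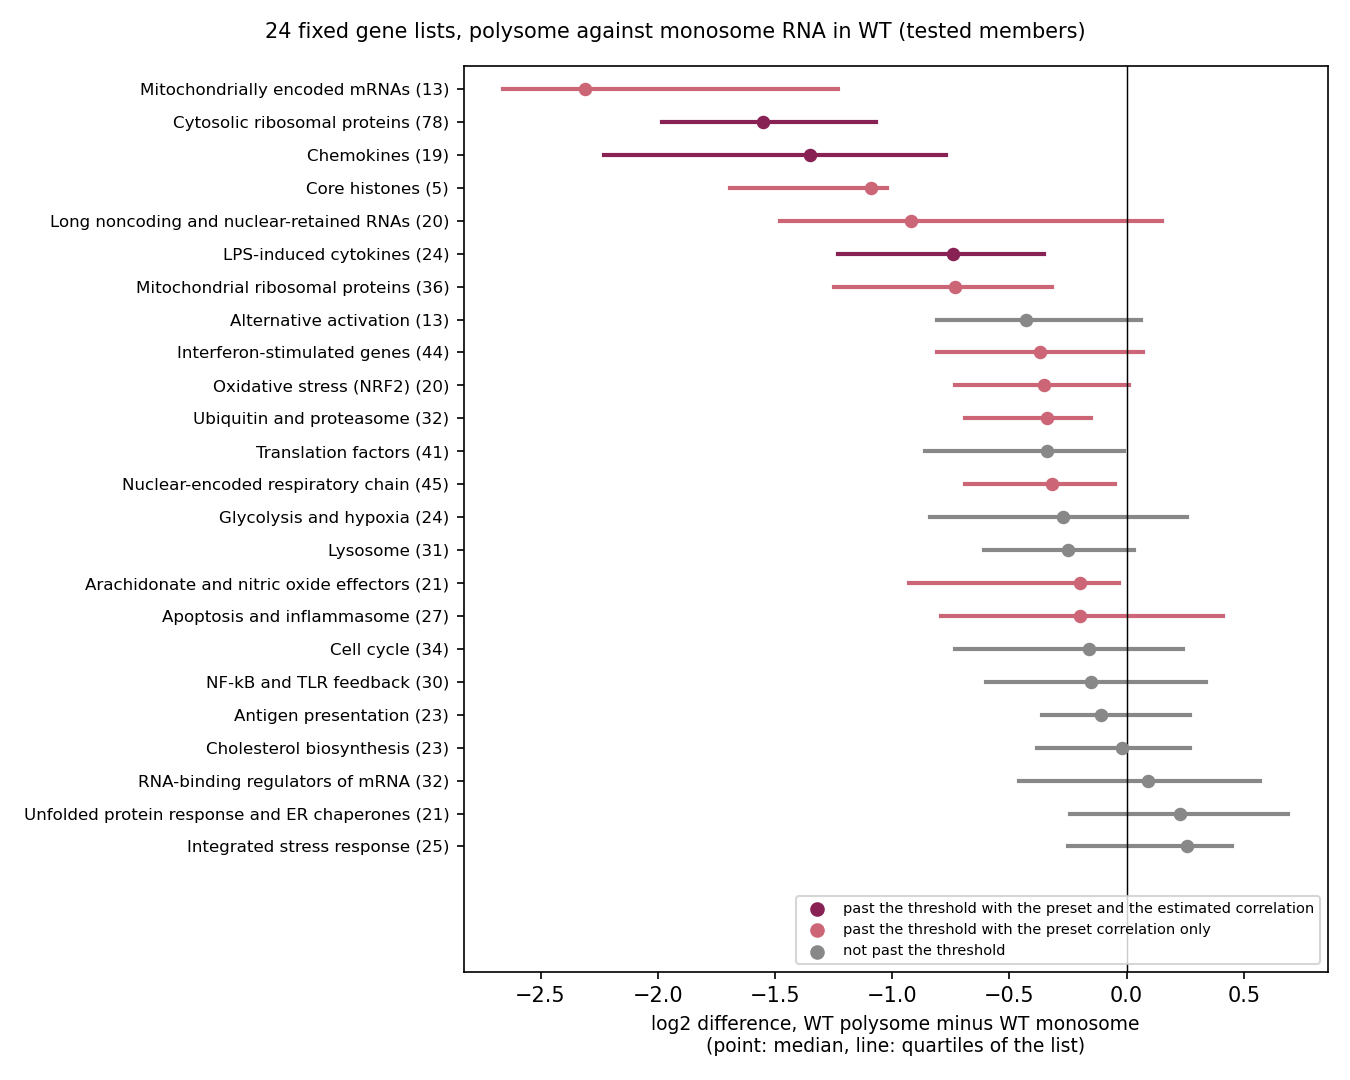
Median (point) and quartiles (line) of the log2 difference between WT polysome and WT monosome RNA (x axis) for 24 fixed gene lists (y axis, with the number of tested members). Colours mark lists past the adjusted p threshold of 0.05 with both correlations, with the preset one only, or with neither. The medians run from -2.31 for mitochondrially encoded mRNAs to 0.26 for the integrated stress response; without library scaling each would lie higher by about 1.01, and the median of the LPS-induced cytokines would be positive.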

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

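In this part the tests of 2-state genes, of Il6, of a swap of libraries and of a retained Mkrn2 transcript, and the counts of other splits, were chosen after the results were seen, and the test of gene overlap was chosen before.

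The effect of the KO label differed between polysome and monosome RNA, by edgeR's interaction term, for 7 genes. The log2 differences of the polysome-to-monosome ratio were 2.57 for the hexokinase Hk1 (adjusted p = 1.29e-09), 2.1 for the chromatin protein Phf3 (3.29e-05), 2.0 for the coactivator Trip4 (0.00301), 1.11 for the import receptor Kpna6 (0.0118) and -1.39 for the amino acid transporter Slc7a7 (0.0327). Fitted values were 5.18 for Aarsd1 (4.35e-08) and 4.88 for Dgcr2 (0.00492). Both rest on KO-labelled monosome libraries with few or 0 counts, whose ratios to WT were 0.0307 (counting interval 0.00822 to 0.0806) and 0.0364 (0.0201 to 0.0608). Of 100 splits of the 12 libraries, the real one included, 50 gave at least the 7 genes, the highest other split giving 13, so a grouping by chance is not excluded for the count. Slc7a7 had adjusted p = 0.118 without WT polysome replicate 1, 0.0578 without WT polysome replicate 2, 0.0526 without WT polysome replicate 3, 0.0973 without KO polysome replicate 2, 0.129 without KO polysome replicate 3, 0.0837 without WT monosome replicate 3 and 0.071 without KO monosome replicate 1. Kpna6 had 0.0505 without WT polysome replicate 2, and without KO monosome replicate 3 Dgcr2 has no KO-labelled monosome count left.

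The large differences in monosome RNA, with Hk1, Phf3, Trip4 and Srrm1 at 4-fold or more, were set against technical explanations. Across the monosome libraries 432 of 7920 genes (5.45%) sat in 2 separate states. So did 205 of 9788 (2.09%) in total and 302 of 9917 (3.05%) in polysome RNA. Simulated counts gave 9, 8 and 7 in these 3 fractions, but they had no spread particular to a gene and are not a matched reference. For part of the differences, a candidate explanation is that genes take such states without regard to genotype. In monosome RNA 5 genes were parted at the genotype labels and 10 at the highest of the other 9 splits. Of the 17 called genes with a log2 difference over 1, 6 were in 2 states, so it leaves the other called genes open. Hk1 was among those in 2 states, at 10.7 to 12.8 CPM with the KO label and 84 to 85.4 in WT. So was Phf3, at 3.71 to 5.28 CPM with the KO label and 15.7 to 21.2 in WT. Reads shared with an overlapping gene cannot be told apart from a genotype effect on ribosome loading, which stays open, because 12 of 32 called genes overlapped another gene (37.5% against 34.8%; odds ratio 1.12, 95% interval 0.5 to 2.41), while the 2-state genes overlapped another gene more often (44.5% against 33.7%, odds ratio 1.58, Fisher's exact test p = 6.72e-06).

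Il6 in polysome RNA, at a log2 difference of 0.90 with all 3 KO-labelled libraries above the WT ones, was set against 3 explanations. The first was RNA from stromal cells, whose 8 markers were higher in polysome RNA too (median 0.46, highest 0.89). If its Il6 parted between total and polysome RNA like these markers, the lower bound of the Il6 rise in polysome RNA (0.58) would need a rise in total RNA. The needed rise was 0.71 (median over the markers, with a lower quartile of 0.67 and a lowest of 0.45), and Il6 had 0.15 there (interval -0.18 to 0.47). That bound takes its spread from all 18 libraries. Il6 stood at 86.6, 129 and 150 CPM in the KO-labelled polysome libraries and at 63.5 to 66.4 in the WT ones. A bound from the polysome libraries alone was not computed, so the values do not decide on stromal cells. Stromal Il6 loaded otherwise stays open too, and in monosome RNA, where the markers had a median of 0.59, Il6 had -0.25 (interval -0.57 to 0.07). A shift of all LPS-induced cytokine mRNAs was argued against by a median polysome-to-total difference of 0.00 over the other 23 cytokines (quartiles -0.06 and 0.05), of which Ifnb1 was highest at 0.7. It does not rest on 1 library, since the difference was 0.72 without KO polysome replicate 3, though with adjusted p = 0.111, and 1.10 without KO polysome replicate 1 (adjusted p = 0.000778), and an effect of the genotype on Il6 loading stays open, as the polysome-to-total ratio did not pass (0.75, adjusted p = 1).

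Mkrn2 RNA in the libraries labelled KO, at 0.888, 0.901 and 0.772 of WT, was set against 2 explanations. If the allele removed the transcript, a swap of libraries between genotypes would leave some libraries with little Mkrn2, and the lowest of all 18 stood at 79.1% of the median of its fraction, the highest at 114%. An allele that keeps the transcript, as one that ends the protein early would, stays open and was not decided, and with it wrong labels, which Mkrn2 levels would not show: the counts of 480 to 1674 in the KO-labelled libraries are gene totals and do not show which exons were read.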

How the results depend on the processing

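The robust prior, the refits of gene lists without each library and the comparison of polysome with total RNA in WT were chosen after the counts were seen; the other settings were fixed before the data were examined. The cause was not tested for any result below that changed sides of the threshold or moved by over 1.5 times. Refits without a library and with only the groups compared use fewer libraries. Those with only the groups compared also take the spread from these groups alone.

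Counts of called genes in total, polysome and monosome RNA (2, 2 and 32) moved with the setting, as did those of the ratios. With RLE size factors polysome RNA had 5 calls. With no filter total RNA had 1 and polysome RNA 5, and polysome RNA had 9 with a strict filter and 9 with the robust prior. With only the groups compared the counts were 1, 8 and 10, and 1 for the polysome-to-total ratio. With the replicate number as a block they were 0 (747 at an unadjusted p under 0.05 by edgeR without the block), 4 and 19. Whether the numbers pair the libraries is not stated, and the residuals of equal numbers correlated at -0.01 to 0.15. The equal number was the best match for 3 of 3 WT and 2 of 3 KO-labelled pairs of total and polysome libraries. For polysome and monosome libraries this held for 1 of 3 and 0 of 3 pairs. Between the labels it held for 2, 1 and 1 of 3 pairs in total, polysome and monosome RNA. Shared cultures of total and polysome libraries thus stay open. Voom with quality weights called 67, 26 and 15 genes and 1 for the polysome-to-total ratio, and DESeq2 32, 55 and 118, with 3 for that ratio and 27 for the polysome-to-monosome ratio (7 by edgeR).

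Without 1 library the counts ran from 1 to 6 in total RNA (1 without WT total replicate 2 or KO total replicate 2, 6 without KO total replicate 1, 5 without KO total replicate 3) and from 1 to 6 in polysome RNA (1 without WT polysome replicate 1 or 2, 6 without WT polysome replicate 3, 5 without KO polysome replicate 1, 4 without KO polysome replicate 3). They ran from 30 to 71 in monosome RNA (71 without WT monosome replicate 1, 56 without WT monosome replicate 2, 52 without KO monosome replicate 3) and from 0 to 4 for the polysome-to-total ratio (4 without KO total replicate 1, 3 without KO total replicate 3, 1 without KO polysome replicate 1, 2 or 3). They ran from 6 to 19 for the polysome-to-monosome ratio (19 without WT monosome replicate 1 or KO monosome replicate 3, 18 without WT monosome replicate 2, 16 and 12 without KO monosome replicates 2 and 1). In WT they ran from 6378 to 6716 for polysome against monosome RNA (5763 to 9950 under the other settings) and from 3162 to 3640 for polysome against total RNA (3651 to 5161).

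Il6 kept its direction throughout. In polysome RNA it was 0.89 with no filter (adjusted p = 0.0389), 0.90 with a strict filter (0.0441), 0.90 with the robust prior (0.0339), 0.84 with voom (0.0317) and 0.89 with DESeq2 (0.000102), all past the threshold, against a range of 0.000102 to 0.403 over the settings. For the polysome-to-monosome ratio it was 1.14 with DESeq2 (adjusted p = 0.00124, range to 0.444). Without 1 library it ran from 0.72 (KO polysome replicate 3) to 1.10 (KO polysome replicate 1, adjusted p = 0.000778) in polysome RNA and from 0.97 to 1.34 for the polysome-to-monosome ratio (adjusted p = 0.00131 without KO polysome replicate 1).

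With an estimated correlation 0 lists passed in each of the 5 genotype comparisons (3, 3, 2, 1 and 1 with the preset one) and 3 of 13 in WT polysome against monosome RNA, where 7 passed without scaling beyond library size. In monosome RNA 1 list passed with the replicate block. Without 1 library the list counts ran from 1 to 6, 3 to 5, 0 to 4, 0 to 2 and 0 to 3 in the genotype comparisons, and from 11 to 14 and 10 to 12 in WT polysome against monosome and total RNA. Of the named genes' values under the other settings, 1002 kept their side of the threshold, 47 passed in addition and 55 no longer passed. An alternative pseudocount was not run, because it was meant for normalised values. Of the 34745 genes 12782 had counts enough to be tested, and 14596 to 16723 had any count in a library. Whether more depth would add genes was not tested.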

Other observations

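In this part the comparison of polysome with total RNA in WT, the tests of the DNA around Mkrn2 and of the mean over the fractions, and the counts of other splits were chosen after the results were seen, while the tests of coding length, of the endoplasmic reticulum and of the second fibroblast list were chosen before.

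In WT cells, mRNAs of ribosomal proteins and of nuclear-encoded mitochondrial proteins were more abundant in polysome than in total RNA, and those of endoplasmic reticulum (ER) chaperones and lysosomal proteins less, under each of the 3 scalings. With an estimated correlation the ER chaperones alone passed among these (adjusted p = 0.0361), and the ribosomal proteins (0.186), respiratory chain (0.253), mitochondrial ribosomal proteins (0.195) and lysosomal genes (0.186) did not. By edgeR 4214 genes passed, 2107 each way. Of 78 ribosomal protein genes 58 rose and 0 fell (median 0.57), such as Rpl41 (1.28 ± 0.13) and Rps15 (1.11 ± 0.11). Of the respiratory chain 32 of 45 rose and 5 fell (0.51), such as Ndufa13 (0.91 ± 0.09), and of the mitochondrial ribosomal proteins 25 of 36 rose and 0 fell (0.54), such as Mrpl36 (0.92 ± 0.12). Of the 13 mitochondrially encoded mRNAs 4 fell and 1 rose (median -0.21), and the list did not pass (adjusted p = 0.289). The first 3 of these lists had adjusted p of 1.21e-19, 1.1e-07 and 2.41e-10 by camera with the preset correlation. Of 21 ER chaperone genes 11 fell and 2 rose (median -0.64, adjusted p = 3.31e-05, and 0.0361 with an estimated correlation), such as Calr (-0.89 ± 0.06) and Pdia6 (-1.0 ± 0.08). Of 31 lysosomal genes 19 fell and 2 rose (-0.35, adjusted p = 2.85e-06, and 0.186 with an estimated correlation), such as Man2b1 (-1.47 ± 0.11), Scarb2 (-0.93 ± 0.09) and Tpp1 (-0.71 ± 0.07). Of the 8 stromal markers 7 fell (-1.10, adjusted p = 1.72e-05, and 0.103 with an estimated correlation). Il6 fell by 0.57 (adjusted p = 0.00916), with Il12b at -0.91 ± 0.13, Nos2 at -0.57 ± 0.08 and the initiation factor Eif4g1 at -1.0 ± 0.06, while the stress-response transcription factors Atf4 (0.72 ± 0.10), Atf5 (0.91 ± 0.14) and Cebpb (0.97 ± 0.14) and Mkrn2 itself (0.56 ± 0.08) rose. The other called lists were chemokines (0.27) and noncoding RNAs (0.37), higher, and interferon-stimulated genes (-0.19), RNA-binding regulators (-0.16), glycolysis (-0.26) and the cell cycle (-0.28), lower; with macrophage markers (-0.37) they had adjusted p from 0.0157 to 0.038. None of them passed with an estimated correlation: adjusted p was 0.376 for chemokines, 0.186 for noncoding RNAs, 0.248 for interferon-stimulated genes, 0.253 for RNA-binding regulators and for glycolysis, 0.184 for the cell cycle and 0.103 for macrophage markers.

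Coding length may account for part of the order of genes between fractions. Its Spearman correlation with the WT polysome-to-monosome difference was 0.40 over 11688 genes, with medians of -0.42, -0.14, 0.14 and 0.44 from the shortest to the longest of 4 equal groups of genes, and -0.50 with the polysome-to-total difference (0.31, 0.01, -0.11 and -0.31). In polysome against monosome RNA it is not the whole cause for chemokines, whose median was -1.35 before and -0.86 after the trend was taken out, nor for ribosomal proteins, at -1.55 and -1.09. In polysome against total RNA the trend was not taken out for ribosomal proteins, the respiratory chain or mitochondrial ribosomal proteins. How far coding length accounts for their higher polysome level was not tested. The median coding length of ribosomal proteins was 462 bases, and the shortest of the 4 groups reached 843. For the 52 ER chaperone and lysosomal genes the median in polysome against total RNA went from -0.38 to -0.28, which does not decide. A loss of mRNAs translated at the ER was not decided either. After the trend was taken out, 24 receptor genes lay above 24 cytosolic ones (-0.09 against -0.24, a difference of 0.14, permutation p = 0.0451). The cytosolic list was itself near the -0.28 of the ER chaperone and lysosomal genes, so a comparison with it cannot exclude such a loss.

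The stromal markers higher with the KO label in all 3 fractions could reflect a larger share of stromal cells. A second list of 19 fibroblast genes had medians of 0.28, 0.30 and 0.20 in total, polysome and monosome RNA, with 16, 16 and 17 higher (camera p of 0.000112, 2.43e-06 and 0.00154, and 0.032, 0.0116 and 0.0697 with an estimated correlation), which lie below the 0.43, 0.46 and 0.59 of the first list and do not decide. In total RNA Col1a1 stood at 55 ± 12.5 CPM in WT and 71.3 ± 3.08 with the KO label, Col1a2 at 84.3 ± 13.6 and 116 ± 5.95, and Dcn at 54.9 ± 4.69 and 61.1 ± 2.77. Il17ra lies 4.86 Mb from Mkrn2, and flanking DNA of another strain could mark such genes. Of 216 tested genes within 20 Mb, 15 had an unadjusted p under 0.05 in total RNA (6.94% against 5.83%; odds ratio 1.21, 95% interval 0.659 to 2.05), which does not decide.

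Of the genes whose libraries did not overlap between the labels there were 1365 of 9788 in total (13.9%), 1580 of 9917 in polysome (15.9%) and 1061 of 7920 in monosome RNA (13.4%). Chance gives 10% on average over splits, but a single split can lie above it. The other splits were not counted, so these shares do not decide on genotype. On the mean over the 3 fractions, taken over libraries of equal replicate number although the labels state no such pairing, 2 genes passed by limma, both lower with the KO label, Hk1 (-1.09) and Aarsd1 (-1.40), with 1369 at an unadjusted p under 0.05. Both means rest on monosome RNA: in total, polysome and monosome RNA Hk1 had -0.21, -0.25 and -2.82, and Aarsd1 had -0.17, 0.22 and -4.96, with the opposite sign in polysome RNA. Of 10 splits, the real one included, 1 reached that count, the highest other giving 1 gene.

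The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real counts of genes and the highest of the other 9 splits, with the number of splits as large as the real one, itself counted, were 2 and 2 in total RNA (2 splits), 2 and 5 in polysome RNA (5 splits), 32 and 23 in monosome RNA (1 split), 7059 and 2 for WT polysome against monosome RNA (1 split) and 4214 and 1 for WT polysome against total RNA (1 split). For lists they were 3 and 9 (8 splits), 3 and 11 (7 splits), 2 and 2 (3 splits), 13 and 9 (1 split) and 11 and 10 (1 split). For the polysome-to-total ratio 0 genes passed by edgeR (229 at an unadjusted p under 0.05, with 1 by voom and 3 by DESeq2), so that all 100 splits give as many by construction and decide nothing (highest other 4). Of the 100 splits, the real one included, 89 gave at least the 1 list for that ratio (highest other 12), and for the polysome-to-monosome ratio 73 gave at least the 1 list (highest other 10), so a grouping by chance is not excluded for these list counts.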
